A study of Mus musculus with 2 samples.

How the data were processed

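Live CD45-positive cells were sorted from orthotopic Hepa1-6 liver tumours of mice treated with anti-PD-1 or isotype antibody, and each group was sequenced as 1 library with the 10x Genomics 3′ v2 chemistry, per the labels' protocols. The deposited values are raw UMI counts per gene and cell barcode, with no normalization, in a sparse matrix of 32285 genes per library. Cell Ranger 5.0.1 made them per the file headers, while the submitters' processing notes name Cell Ranger 2.1.1, and the genome build is mm10 per the same notes. The deposited matrices hold called cells only, with at least 500 UMIs per barcode, and the settings of cell calling are not given in the sources used here. A dense table of each library was compared with its matrix, and 0 values differed, so the tables were not used further. Total depth was 72148493 UMIs in the anti-PD-1 library and 67520433 in the isotype library. How many mice went into each library is not given in the sources used here.

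Cells were kept with at least 500 UMIs, at least 200 genes and at most 10% of UMIs from mitochondrial genes, which left 10014 of 10149 and 9566 of 9683 barcodes. Doublets were scored per library with scrublet as implemented in scanpy 1.11.5, at an expected rate of 0.06. The automatic threshold marked 0 barcodes in either library, so scores above 0.25 were called doublets. That value was chosen after the scores were seen, and it removed 302 (3.02%) and 280 (2.93%) barcodes. The 9712 and 9286 kept cells of both libraries were clustered together: counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen without mitochondrial, ribosomal protein and immunoglobulin or T cell receptor variable genes, and 30 principal components and 15 neighbours entered Leiden clustering at resolution 1.0 with 1 fixed seed. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9, matplotlib 3.10.9 and R 4.3.3 were used.

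Clusters were named by markers of 24 cell types, from the type with the highest mean marker score among those with at least 3 markers detected in at least 10% of cells. A cluster stayed unnamed if 3 times its median UMI count was below the median of all kept cells in both libraries and none of its type's markers was among its 10 leading genes by fold, which left cluster 5 unnamed. The fold used a pseudocount of 1, and this rule was settled after another pseudocount and detection share had been looked at. T and NK-like cells were clustered again on their own. Their sub-clusters with at least 3 proliferation or histone genes among the leading 10 were called cycling, and those with Lyz2 in at least 50% of cells or with more markers of another type than of their own were left unnamed. Monocyte and macrophage clusters were pooled by number, since cluster 1 had 1 marker of cDC2 and none of monocytes among its leading genes. Classes with at least 200 cells in each library were compared, and, as added after the data were seen, subsets, smaller classes and single clusters with at least 50.

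The markers, the gene lists, the filters on cells, the comparisons, the rule for named genes and the first set of alternatives were fixed before the data were examined. With 1 library per group no test between the antibodies was possible, and cells were not treated as replicates. Shares of cells are given with exact Clopper-Pearson 95% intervals and their differences with Newcombe 95% intervals. UMIs were summed per class and library and scaled to CPM of the class total, and log2 ratios carry exact conditional binomial 95% intervals. A gene with 0 UMIs in 1 library was set against a floor of 3 counts over the class. For each of 19 gene lists, the median log2 ratio of members with at least 10 UMIs over both libraries was taken where at least 3 members were measured. Its counting interval comes from 1000 Poisson draws, and its percentile from 10000 random lists of the same size matched on mean expression in 20 bins. Mx1 is not among the features, and Cd244 was matched to Cd244a. Shares of cells with a UMI were computed after thinning each cell to 1000 UMIs without replacement, which left out shallower cells, with B and plasma-like cells as background. Intervals cover counting error only, and the percentiles describe these 2 libraries.

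Named genes were ranked by the bound of their interval nearest to 0, among genes with at least 50 UMIs in the class and at least 20 CPM in the higher library. Mitochondrial, ribosomal protein, haemoglobin, sex-linked, receptor segment and unnamed gene models and markers of other classes were left out. The 10 highest and 10 lowest genes were taken in the 3 classes with most cells and the 3 highest and 3 lowest in the other 2. Every member of a fixed list could be named too. Positions come from GENCODE vM21 on the same genome build, in which all 268 looked-up gene identifiers were found.

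Alternatives fixed in advance were mitochondrial limits of 5% and 20%, a minimum of 1000 UMIs, no doublet removal, resolutions 0.5 and 2.0, classes from marker scores of single cells, TMM scaling with edgeR 4.0.16, averaging each cell's CPM, thinning of the UMI sums, a minimum of 50 UMIs per list member, and shares of cells with a UMI after thinning to 500 or 2000 UMIs or without thinning. Chosen after seeing the data were clustering without interferon-induced genes, sub-clusters of T and NK-like cells, CD8 T cells counted from genes or with an unnamed sub-cluster of best CD8 score added, thinned list medians, leaving out the Ngp and Camp-led cluster, the Lyz2-carrying sub-cluster or the cell with most UMIs of a gene, random lists matched on transcript length, all counts of barcodes with 2 kinds of RNA, and a comparison of UMIs per cell between classes as a test of free RNA. The minimums for those barcodes were 2 T cell, 3 monocyte-macrophage and 3 neutrophil genes. They were run after a first count with other minimums, so all minimums of a grid are reported. The comparisons by transcript length and GC content were added after a shift of short ribosomal protein genes had been seen.

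The interval calculation was tested on simulated counts with 200 changed genes. These were independent Poisson draws without variation between cells, the model behind the interval. They check the calculation only, and do not cover UMIs gathered in single cells or genes that vary together. At the depth of all cells the interval held the true ratio for 96.0% of genes changed 2-fold and 95.5% of genes changed 1.5-fold among 12746 genes, and at 5% of those UMIs for 96.0% and 96.5% among 7759 genes, with the right sign for 100% and 98.5%. Of 200 unchanged lists of 20 genes, 3.0% fell outside the middle 95% of random lists.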

Results

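Gene expression was measured in single live CD45-positive immune cells sorted from liver tumours that grew in C57/BL6 mice after implantation of Hepa1-6, a mouse hepatoma cell line. The mice received either an antibody against PD-1, the inhibitory receptor encoded by Pdcd1, or an isotype control antibody. Each group is 1 droplet library, so the data hold no replicates, and every interval given here covers counting error only. The anti-PD-1 library held 10149 barcodes with 72148493 unique molecular identifiers (UMIs) and the isotype library 9683 barcodes with 67520433 UMIs. After filtering, 9712 and 9286 cells were kept, with medians of 6304 and 6123 UMIs and 1919 and 1791 genes per cell. The question the comparison addresses is how tumour-infiltrating immune cells differ under PD-1 blockade. Ratios are anti-PD-1 over isotype on the log2 scale, from CPM, the UMIs of a gene scaled to the summed UMIs of its class of cells. Positions are 1-based on mm10.

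Myeloid cells made up most of both libraries. Clusters 0, 1, 4, 8, 12 and 15, which carried monocyte and macrophage markers, held 52.5% of cells in the anti-PD-1 library and 50.4% in the isotype library, a difference of 2.09 percentage points (95% Newcombe interval 0.671 to 3.51). Of these, clusters 1 and 4 held more cells in the anti-PD-1 library, and clusters 0, 8, 12 and 15 held fewer. The higher share rests on cluster 1, since without it the remaining clusters together held a smaller share in the anti-PD-1 library. Neutrophil-like cells made up 19.2% and 20.2% (interval of the difference -2.13 to 0.132 points). Over 8 alternatives that difference lay between -2.21 and -1.31 points. Dendritic cells of the cDC2-like class, which present antigen mainly to CD4 T cells, made up 5.15% and 5.88% (difference -0.732, -1.38 to -0.0824). Over 8 alternatives that difference lay between -0.749 and -0.172 points. The cDC1-like cells, specialised in cross-presentation, made up 1.62% and 1.32%, with a difference between 0.146 and 1.58 points over 7 alternatives. Non-classical monocyte-like cells, the patrolling monocytes, made up 5.33% and 4.59% (difference 0.746, 0.128 to 1.36), but 7.67% and 7.78% with a mitochondrial limit of 20%. An unnamed cluster of low-UMI cells (cluster 5, best scored as neutrophil) held 6.31% and 7.83%. With it, neutrophil-scoring clusters held 25.5% and 28.0%. The CD45 sort sets which cells could be seen, so these are shares of sorted immune cells and not of the tumour.

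CD8 T-like cells, the killer T cells, were the T cell subset that differed most in relative size. Their sub-cluster, led by Cd8b1, Cd8a, Ly6c2, Gzmk and Gzmb, held 91 cells or 0.937% (exact 95% interval 0.755 to 1.15) in the anti-PD-1 library and 26 cells or 0.280% (0.183 to 0.410) in the isotype library. Counted without clusters, from at least 2 T cell genes and Cd8a or Cd8b1 without Cd4 in a cell, the numbers were 203 and 75 cells, or 2.09% and 0.808%, a difference of 1.28 points (0.948 to 1.63). CD4 T-like cells, the helper T cells, lay in the other direction at 1.89% and 2.40% (difference -0.507, -0.924 to -0.0946), with a difference of -0.165 when counted from genes. Regulatory T-like cells made up 0.772% and 0.722%, NK-like cells 0.721% and 0.883%, and gamma-delta T-like cells, led by Il17a, 0.391% and 0.625%. Cycling T and NK-like cells numbered 105 and 60, or 1.08% and 0.646% of all cells. T and NK-like cells together made up 7.23% and 6.62% (difference 0.605, -0.118 to 1.33).

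**Figure D1:**
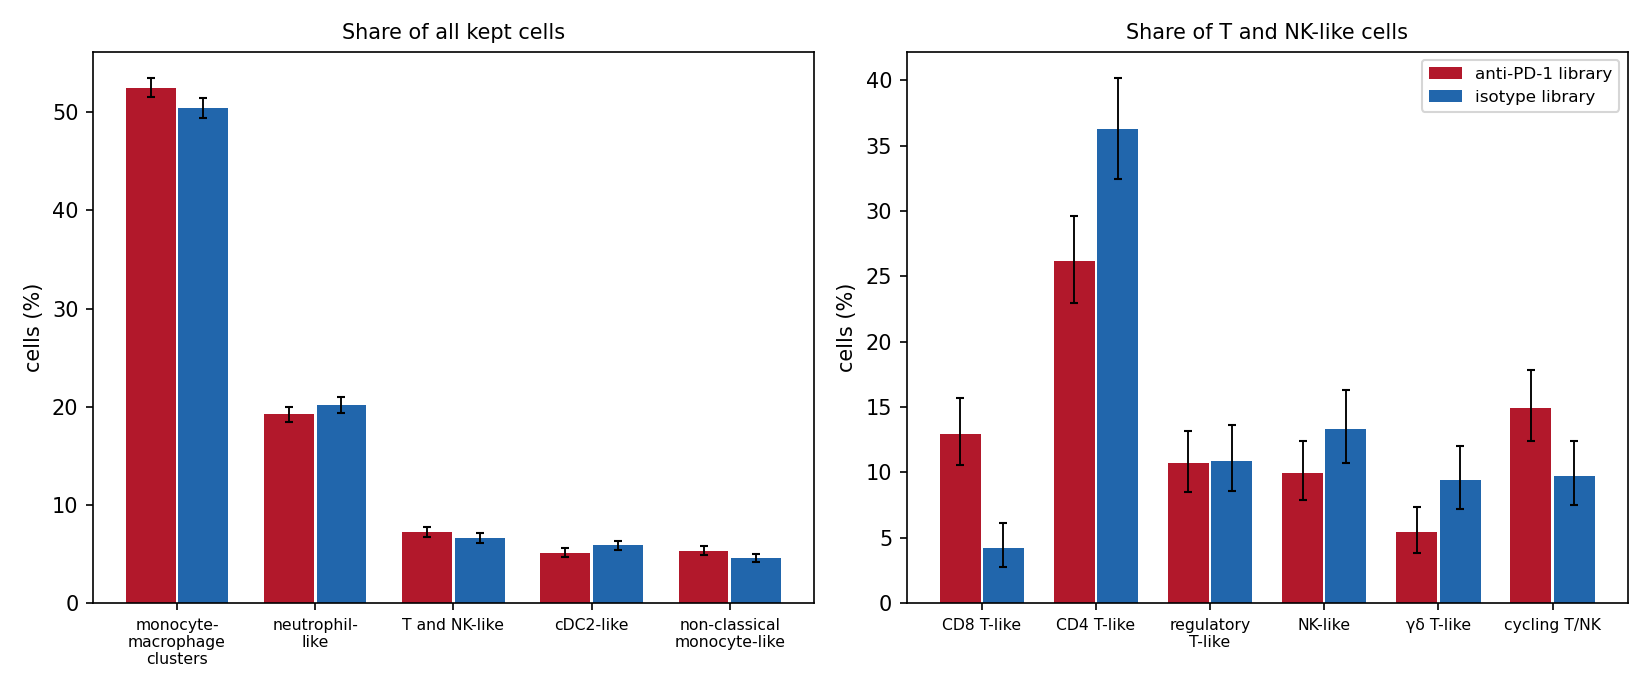
Shares of cells per class in the 2 libraries, of all kept cells (left) and of T and NK-like cells (right), in percent, with exact 95% binomial intervals as error bars that cover counting error only. CD8 T-like cells were 91 of 702 T and NK-like cells in the anti-PD-1 library and 26 of 615 in the isotype library.

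In the monocyte and macrophage clusters, genes induced by interferon-gamma, the main macrophage-activating cytokine of T and NK cells, were higher in the anti-PD-1 library. All 22 measured members of the interferon-gamma response list had higher CPM there, with a median log2 ratio of 0.81 (counting interval 0.79 to 0.86). Gbp2, a guanylate-binding protein of cell-autonomous defence (ENSMUSG00000028270, chromosome 3, 142620602 to 142638008), stood at 432 against 191 CPM (1.18, 1.14 to 1.22). Gbp5 (ENSMUSG00000105504, chromosome 3, 142493978 to 142522344) had a log2 ratio of 1.37, the transcription factor Irf1 0.81, and Cd274, which encodes the PD-1 ligand PD-L1 (ENSMUSG00000016496, chromosome 19, 29367455 to 29388095), 0.39. The chemokines Cxcl9 and Cxcl10, which attract T cells through Cxcr3, had ratios of 0.55 and 0.86. All 17 measured type I interferon response genes (median 0.54) and all 11 MHC class I genes (median 0.39) were higher too, with Isg15 at 419 against 297 CPM and H2-K1 at 1160 against 943 CPM. The list median lay at percentile 100 among 10000 random lists of matched expression for all 3 lists, as a description of these 2 libraries.

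Since cluster 1 is led by Cxcl9, Gbp2 and Ly6a and carries no monocyte marker among its 10 leading genes, the clusters were also compared one by one. The median of the interferon-gamma response list was 0.45 in cluster 0 (led by C1qb and Apoe), 0.42 in cluster 1, 0.51 in cluster 4 (led by Chil3 and Ly6c2), 0.34 in cluster 8 (led by heat-shock genes), 0.29 in cluster 12 (led by Ccl24 and Arg1) and -0.028 in cluster 15 (led by Thbs1 and Fn1). The value over all 6 clusters is larger than any of these. The 2 libraries spread their cells differently over the clusters: cluster 4 held the most cells of the class in the anti-PD-1 library and cluster 0 in the isotype library, and cluster 1 made up a larger part of the class in the anti-PD-1 library. The pooled value therefore holds this difference in make-up together with differences within clusters, and cannot be read as a change of expression within 1 kind of cell. No sizes are given, since the genes that define cluster 1 themselves differ between the libraries. When the cells were clustered without interferon-induced genes the pooled value was 0.81. That value pools all clusters of the class again, so it cannot separate make-up from differences within clusters.

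Suppressive and repair macrophage genes were lower in the anti-PD-1 library when the same clusters were pooled, which differ in make-up: 14 of 17 were lower and 3 higher, with a median of -0.23 (-0.31 to -0.18, percentile 0). Arg1, the arginase that depletes arginine (ENSMUSG00000019987, chromosome 10, 24915221 to 24927484), stood at 1134 against 1568 CPM (-0.47), the mannose receptor Mrc1 at 30.6 against 50.2 CPM (-0.71) and the elastase Mmp12 at 227 against 349 CPM (-0.62), while Il10, an anti-inflammatory cytokine, was higher (0.69). Within single clusters the difference mostly disappeared, with medians from -0.11 in cluster 1 to 0.040 in cluster 15. Inflammatory myeloid genes were higher for 12 of 13 members (median 0.26, 0.21 to 0.31, percentile 100), among them Tnf (0.62), Ptgs2, which makes prostaglandins (0.38), and Il1b (0.19), and within clusters the median lay between 0.12 and 0.40. MHC class II genes differed little, with a median of -0.035 that was 0.028 with each cell's CPM averaged and 0.017 after thinning.

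Of the 10 higher genes named by the size rule in these clusters, 5 belong to the interferon-gamma response list. The ratios and shares given here pool the clusters, whose make-up differs between the libraries. They cannot be read as changes of expression within 1 kind of cell. Higher were Ly6a, encoding Sca-1 (ENSMUSG00000075602, chromosome 15, 74994877 to 74998031), at 394 against 146 CPM (1.44), Calhm6 (1.41), Gbp6 (1.45), Tgtp2 (1.45), Ly6i (1.20), Igtp (1.26), Gbp4 (1.19) and Il18bp, the interleukin-18 antagonist (1.25). Lower was the heat-shock protein gene Hspb1 (-0.96), which had UMIs in only 106 of 5100 and 146 of 4682 cells. Also lower were the metallothionein gene Mt2 (-0.79), Acp5 (-0.79, and -0.48 without 1 isotype cell that held 691 of its UMIs), the eosinophil chemokine Ccl24 at 871 against 1441 CPM (-0.73), Tnfrsf9 (-0.71), Pltp (-0.66) and Lcn2 (-0.58, and 0.19 after thinning). Atp5k (-0.55) was lower in all 5 compared classes. After thinning to 1000 UMIs, Arg1 was detected in 33.8% of cells against 44.0% and Cxcl9 in 11.5% against 7.19%. Unthinned shares were 47.3% against 58.6% and 20.1% against 12.6%. B and plasma-like cells gave backgrounds of 1.92% and 3.77% for Arg1 and of 1.92% and 0% (0 of 53 cells) for Cxcl9, thinned in the same way. Median depths were 7629 and 7945 UMIs in the clusters and 4370 and 3911 in B and plasma-like cells, and thinning left out 112 and 187 cells of the clusters.

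**Figure D2:**
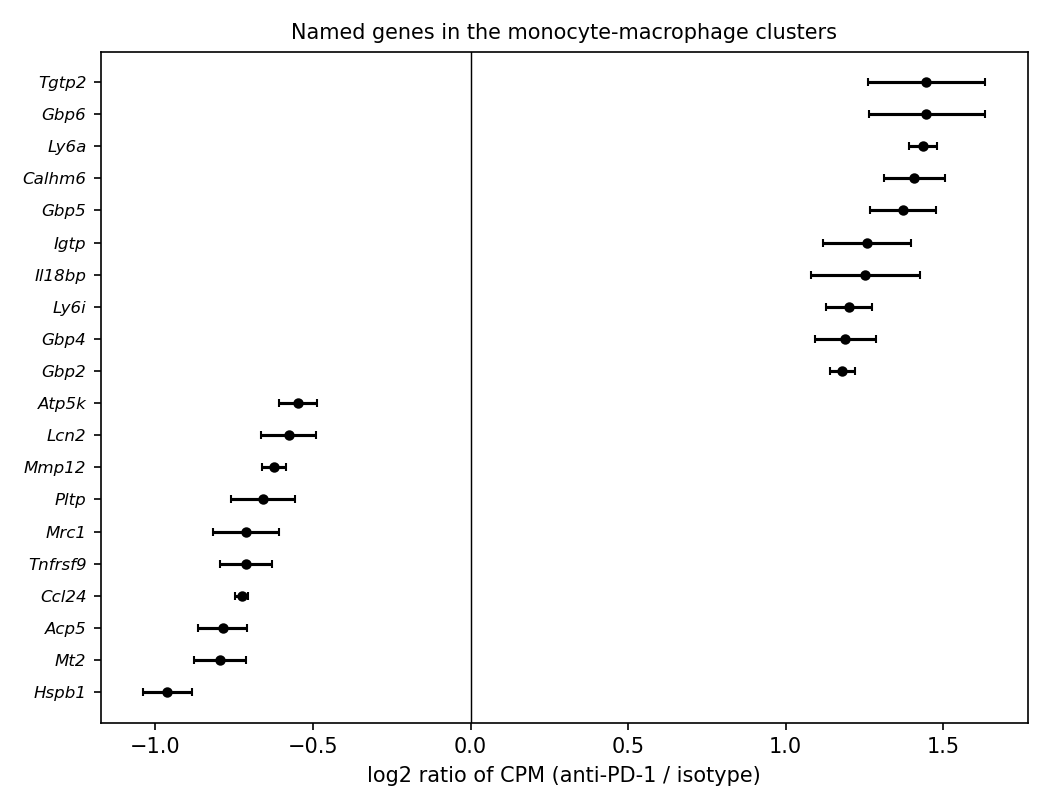
Log2 ratios (anti-PD-1 over isotype, CPM) of the named genes in the monocyte and macrophage clusters, with exact 95% intervals for counting error. The 10 higher genes lie between 1.18 and 1.45 and the 10 lower genes between -0.96 and -0.55. The clusters are pooled, and their make-up differs between the libraries.

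Neutrophil-like cells also had higher interferon-gamma response genes in the anti-PD-1 library, 17 of 18 measured members (median 0.95, 0.73 to 1.08, percentile 100). The value is pooled over the class. Its clusters were not compared one by one, so a difference in make-up may be part of it. Cxcl10 (ENSMUSG00000034855, chromosome 5, 92346638 to 92348889) stood at 288 against 107 CPM (1.42), Gbp5 had a ratio of 1.52, Irgm1 1.28, Gbp2 1.19, Irf1 1.11 and the interferon-induced GTPase Ifi47 1.46. Cd274 stood at 598 against 418 CPM (0.52), and Saa3, an acute-phase serum amyloid gene, had 214 against 35 UMIs (2.69). Some of these genes rest on few cells: Cxcl10 had UMIs in 130 of 1866 and 87 of 1877 cells, and Saa3 in 35 and 14. All 16 type I interferon genes (median 0.58) and all 11 MHC class I genes (0.37) were higher, as were 11 of 12 inflammatory genes (0.35, and 0.19 at resolution 2.0), 6 of 8 checkpoint ligand genes (0.28, and 0.092 with each cell's CPM averaged) and all 16 dissociation and stress genes (0.41, and 0.21 without cluster 16), which respond to tissue handling. Igkc and Igha, immunoglobulin genes, met the size rule from 1 cell of the anti-PD-1 library that held 254 of 257 and all 164 of their UMIs there.

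Genes of immature neutrophils were lower in the anti-PD-1 library. All 11 granule genes were lower (median -0.58, -0.62 to -0.52), led by Camp, the cathelicidin gene (ENSMUSG00000038357, chromosome 9, 109847379 to 109849617), at 3110 against 6042 CPM (-0.96), and so were all 15 proliferation genes (-0.55) and all 6 MHC class II genes (-0.93). Histone genes Hist1h2ae (-2.34), Hist1h2ap (-1.70) and Hist1h1d (-1.91), Pclaf (-1.24), Crip1 (-1.43), Orm1 (-1.54), Fcnb (-1.33), Lyz2 (-1.05) and H2-Aa (-1.23) were named as lower, and Cstdc5 as higher (1.16). The sizes of several depend on the processing: over 8 alternatives Hist1h2ae lay between -2.35 and -0.56, Hist1h2ap between -1.71 and -0.64, Hist1h1d between -4.03 and -0.16, Pclaf between -3.52 and -1.03 and Crip1 between -1.45 and -0.35, and the proliferation median was -1.81 at resolution 2.0. Much of this rests on cluster 16, led by Ngp and Camp, with 86 and 122 cells. Without it the granule median was -0.28, the proliferation median 0.22 and the MHC class II median 0.11, Orm1, Fcnb and Cstdc5 changed sign (0.60, 0.86 and -0.81), and Lyz2 and H2-Aa stood at -0.15 and -0.14. The interferon-gamma median stayed between 0.78 and 1.14 under all 8 alternatives run.

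cDC2-like cells had 20 of 22 interferon-gamma response genes higher (median 0.53, 0.40 to 0.60, percentile 100), with the immunity-related GTPase Iigp1 (1.65) and Tgtp1 (1.40, and 0.93 after thinning) among the named genes. Pmepa1, a target and inhibitor of TGF-beta signalling (ENSMUSG00000038400, chromosome 2, 173224458 to 173276533), stood at 89.0 against 32.5 CPM (1.45). Chemokine genes lay the other way, with 8 of 11 lower (median -0.39, -0.47 to -0.16, and -0.17 after thinning): Ccl17, a ligand of Ccr4 (ENSMUSG00000031780, chromosome 8, 94810453 to 94812036), stood at 447 against 1043 CPM (-1.22), and Ccl22, which binds the same receptor, had a ratio of -0.72. Cxcl3 (-1.30, and -1.86 at resolution 2.0) was lower as well, and 9 of 13 suppressive and repair genes (median -0.27, between -0.51 and -0.13 over 7 alternatives). Ccl24 (-1.84) stood at -0.29 at resolution 2.0 and at -0.96 without 1 isotype cell. TMM scaling lowered all ratios in this class by 0.11 log2, which is the one shift above 0.1 among the 5 classes.

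Non-classical monocyte-like cells had 15 of 19 interferon-gamma response genes (median 0.32, 0.21 to 0.42) and all 7 MHC class II genes (0.21, and 0.12 without doublet removal) higher, and Ly6a (1.12) and Cxcl10 (1.04) were named. All 14 hypoxia and glycolysis genes were lower (median -0.12, -0.18 to -0.072), and 7 of 11 inflammatory genes (-0.21, and -0.034 after thinning), opposite in sign to the monocyte and macrophage clusters; the difference between the classes was not tested. Arg1 (-1.23) and Spp1, encoding osteopontin (-0.94), were named as lower, with Arg1 between -1.72 and -0.42 over 7 alternatives, the latter at a mitochondrial limit of 5%, and Spp1 at -0.34 without 1 isotype cell and 0.22 after thinning. Brd1 (1.21) and Ndufb1-ps (-0.56) were named too. Brd1 was higher in all 5 classes, by 1.01 to 1.25.

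**Figure D3:**
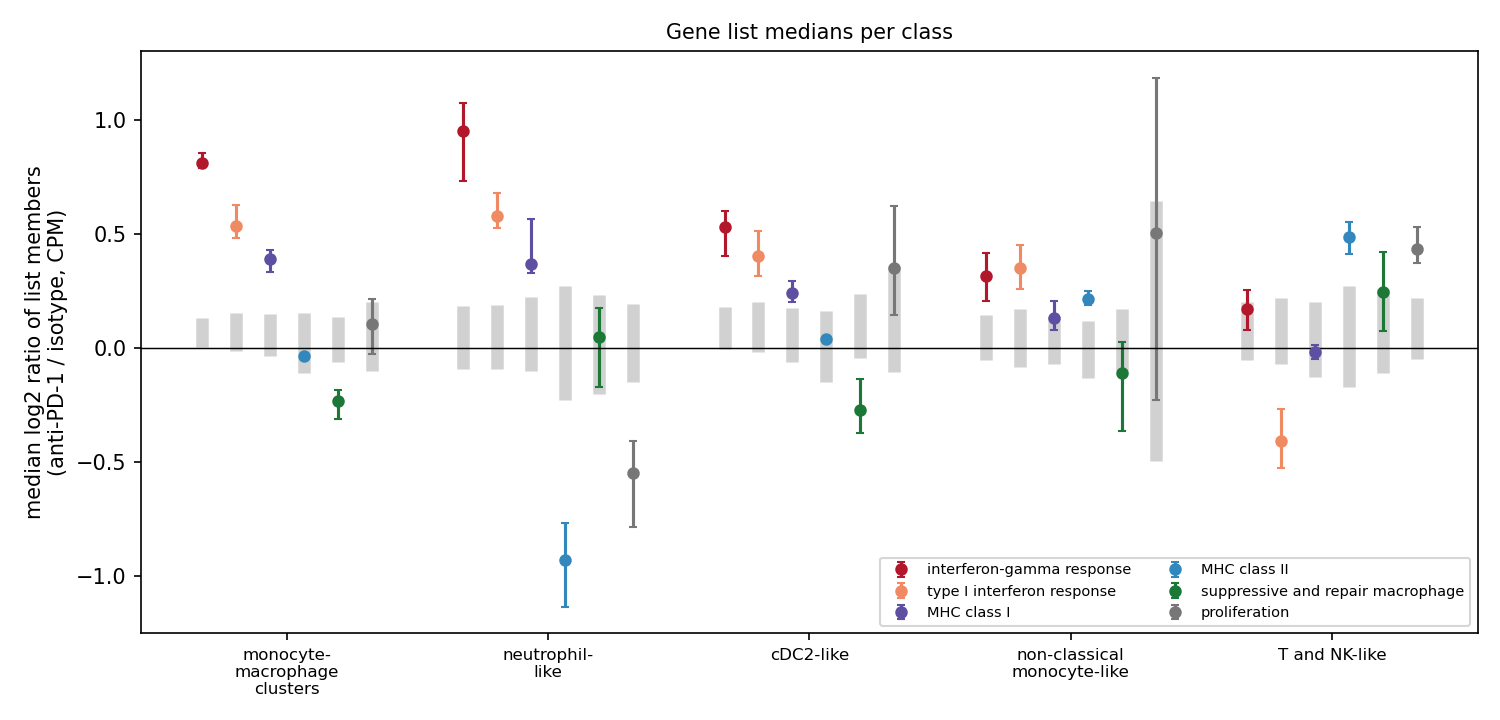
Median log2 ratio (anti-PD-1 over isotype, CPM) of 6 gene lists in 5 classes; error bars are 95% counting intervals and grey bars the central 95% of 10000 random lists of matched expression. The interferon-gamma response median is 0.81 in the monocyte and macrophage clusters, 0.95 in neutrophil-like cells, 0.53 in cDC2-like cells, 0.32 in non-classical monocyte-like cells and 0.17 in T and NK-like cells.

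T and NK-like cells carried more transcripts of inhibitory receptors in the anti-PD-1 library. Of 13 genes of the inhibitory receptor and exhaustion list 10 were higher (median 0.42, 0.28 to 0.49, percentile 100): Pdcd1, the antibody's target (ENSMUSG00000026285, chromosome 1, 94038305 to 94052553), stood at 349 against 207 CPM (0.76), Lag3 at 200 against 119 CPM (0.75) and Tox, a transcription factor of exhausted T cells, at 75.5 against 52.4 CPM (0.53), while Cd244a was lower (-0.79). The list was also higher within CD4 T-like (0.57), regulatory T-like (0.41), cycling (0.45) and NK-like cells (0.27, -0.027 to 0.51). CD8 T-like cells were too few in the isotype library for this comparison. After thinning, Pdcd1 was detected in 22.6% of T and NK-like cells against 16.7% (58.3% against 44.6% unthinned) and Lag3 in 12.4% against 8.70% (45.6% against 30.2% unthinned). The backgrounds in B and plasma-like cells were 0% (0 of 52 cells) and 1.89% for Pdcd1 and 3.85% and 0% (0 of 53 cells) for Lag3. Median depths were 7471 and 6058 UMIs in T and NK-like cells, and 7 and 17 of them were left out by thinning.

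Cytotoxic genes went both ways, with 9 of 16 higher and 7 lower (median 0.15, 0.062 to 0.22, percentile 91.7). That median was 0.034 after thinning and 0.28 with each cell's CPM averaged. Gzmk, a granzyme of memory-like CD8 T cells (ENSMUSG00000042385, chromosome 13, 113171608 to 113225908), stood at 218 against 69.9 CPM (1.64), Gzmb at 1252 against 782 CPM (0.68), Gzma at 1213 against 676 CPM (0.84) and Ccl3 at 531 against 212 CPM (1.32). Ifng (-0.36) and Tnf (-0.61), cytokine genes, were lower. In CD4 T-like cells 13 of 16 cytotoxic genes were higher (median 0.69, 0.50 to 0.91), with Gzmk at 2.06 and Gzmb at 1.23. More CD8 T cells were counted from genes than the CD8 T-like sub-cluster held. Whether some of them lie among the CD4 T-like cells and add to these values was not tested. In regulatory T-like cells 8 of 12 were higher (median 0.31, -0.083 to 0.49), but Gzmb (-0.93), Ifng (-1.93) and Klrg1 (-0.89) were lower and Gzmk had 2 against 25 UMIs. The lower Gzmb sum there does not show by itself that fewer cells carried Gzmb. A Gzmb UMI was found in a larger share of regulatory T-like cells (75 and 67) in the anti-PD-1 library. The difference was 6.41 to 8.56 points over 3 alternatives of thinning. It is given without an interval, and with so few cells counting error alone may cover it. The difference between the subsets was not tested. Gzmb was detected after thinning in 31.8% against 18.9% of T and NK-like cells (52.1% against 34.6% unthinned), with 0 of 52 and 0 of 53 B and plasma-like cells as background. Gzmk and Cd8b1 (1.32) are leading genes of the CD8 T-like sub-cluster, whose share also differed.

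Genes of naive and memory T cells were lower for 8 of 11 members (median -0.22, -0.37 to -0.090, percentile 0.02), including Tcf7, a transcription factor of stem-like T cells (-0.60), and Il7r (-0.65). All 15 proliferation genes were higher (0.43, 0.37 to 0.53). Both values are pooled over subsets whose shares differ, with 105 against 60 cycling cells: the proliferation median was 0.24 in CD4 T-like, -0.12 in cycling, -0.70 in NK-like and -0.90 in regulatory T-like cells, and the naive and memory median -0.30 in CD4 T-like and 0.18 in NK-like cells. Type I interferon genes were lower for 11 of 16 (median -0.41, -0.53 to -0.27), with Isg15 at 754 against 1303 CPM. That median was -0.22 with each cell's CPM averaged and -0.055 after thinning. Its sign is opposite to that in the monocyte and macrophage clusters and neutrophil-like cells, a difference that was not tested, and the interferon-gamma list had a median of 0.17 (0.078 to 0.26). The lymphotoxin gene Lta (-1.42) was lower.

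Some named genes in T and NK-like cells rest on few cells. Cxcl9 (3.20), Tgfbi (1.69), Aif1 (2.41), Ly86 (1.82) and Ms4a6c (1.52), genes of myeloid cells, were higher, but a sub-cluster of 58 and 19 cells carried T cell genes together with Lyz2. Without it Cxcl9 stood at -0.91, Tgfbi at -0.010, Aif1 at 1.74 (0.86 without doublet removal), Ly86 at 1.03 and Ms4a6c at 0.32, and the MHC class II median was -0.72 instead of 0.49. Serpine2 (1.49, and 0.93 after thinning) and Sppl3 (1.60) were also higher, the latter in all 5 classes. Among the lower genes, Gzmf (-6.82), Gzmg (-4.45), Gzme (-1.76), Gzmd (-1.40) and Cd55 (-1.59) owed most of their isotype UMIs to 1 cell with 56379 UMIs. Without that cell Gzmf stood at 1.05 (0.18 to 1.99) and Cd55 at 0.21 (-0.36 to 0.79), and Gzmc at -0.95 instead of -1.41 (-0.65 with each cell's CPM averaged). Gzme then had 291 against 1 UMI (7.62, 5.13 to 12.92) and Gzmd 799 against 1 (9.07, 6.59 to 14.38). Gzmg had 330 against 0, a log2 ratio of 6.21 against a floor of 3 counts over the class (lower bound 5.905). The anti-PD-1 UMIs of these 3 genes come from 3, 3 and 2 cells, so neither direction describes the class. Mcpt1 and Mcpt4, mast cell protease genes, had 248 and 149 UMIs in 2 and 3 isotype cells and 0 in the anti-PD-1 library, and the mast cell chymase gene Cma1 7 against 171 UMIs (-5.16, and -1.56 without 1 isotype cell that held 157).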

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

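Chosen only after the result was seen were both tests of barcodes with T cell and monocyte-macrophage RNA, the test of CD8 T-like cells as a share of T and NK-like cells, the test of free RNA by UMIs per cell, and the comparison of libraries per group. The predictions of the other tests below were written before the results of those tests were seen. Their thinned list medians, random lists matched on transcript length and count of CD8 T cells from genes were themselves chosen after the data were seen.

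Among the barcodes removed as doublets, which enter only the alternatives without doublet removal and the counts given here, 65 in the anti-PD-1 library and 39 in the isotype library held T cell together with monocyte-macrophage RNA, and they stand out as a signal outside the comparisons of the report. Over all barcodes that passed the filters there were 167 and 71, or 0.402 and 0.223 of the number given by the product of the 2 single frequencies. Their ratio between the libraries was 1.80 (lower bound 1.36), the highest of 15 sets of gene minimums (1.19 to 1.80), and the quotient of observed over product between this pair and T cell with neutrophil RNA in the anti-PD-1 library had a lower bound of 1.55, although both pairs lay below the product. With at least 2 T cell genes the first bound lay above 1 in 10 of 10 sets and the second in 30 of 30, with 1 T cell gene in 1 of 5 and 3 of 15, and without Ly6c2 and Plac8 in 8 of 10 and 30 of 30 against 0 of 5 and 0 of 15. Chance capture of 2 cells and T cells attached to macrophages cannot be told apart, since the minimums were chosen after the data were seen, bounds as low as 0.986 remain with at least 2 T cell genes, and neutrophil-like cells have fewer UMIs to be detected by, with medians of 2060 and 1904 against 7629 and 7945.

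The interferon-gamma response list was higher in the anti-PD-1 library in the monocyte and macrophage clusters, by a median of 0.81 on the log2 scale over all clusters pooled, less within 5 of the 6 clusters, and with no rise in cluster 15 (-0.028). The median was 0.83 after thinning to 1000 UMIs, but this cannot decide on a difference in depth, since ratios of CPM already scale depth out. Median depths in these clusters were 7629 and 7945 UMIs. Loss of short transcripts is argued against by percentile 100 among random lists matched on expression and transcript length. Free RNA in the droplets as the whole cause is argued against by UMIs per cell, of which it adds like numbers to every droplet. The difference in neutrophil-like cells was 0.255 of that in these clusters as a median over members (upper bound 0.270), and 0.023 in the unnamed low-UMI cluster. This quotient was 0.227 in non-classical monocyte-like, 0.091 in B and plasma-like, 0.5 in CD4 T-like, -0.041 in regulatory T-like and -0.037 in NK-like cells. It was 1.09 (0.713 to 1.19) in T and NK-like, 1.26 (0.97 to 1.44) in cDC2-like, 1.28 in cDC1-like, 1.39 in cycling and 0.796 in migratory dendritic cells. Those classes do not argue against free RNA. They do not argue for it either, since UMIs per cell also follow depth. Median depths were 7471 and 6058 UMIs in T and NK-like cells and 17866 and 14246 in cycling cells. The quotient of CPM differences in neutrophil-like cells, 0.776, lay between the bounds set for either outcome, and a smaller contribution is not excluded. With 1 library per group, a difference between the libraries other than the antibody and an effect of the antibody cannot be told apart, because each antibody has its own library. An effect of PD-1 blockade on interferon-gamma signalling may add to this pattern and was not tested.

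The share of CD8 T-like cells was higher in the anti-PD-1 library. Placement of cluster borders is argued against by the count from genes in each cell, whose difference had a lower bound of 0.948 percentage points. That count was made without thinning, and median depths were 7471 and 6058 UMIs in T and NK-like cells. It also did not leave out cells with myeloid RNA, so part of its size may come from depth or such cells. More T and NK-like cells of every kind is argued against by the share among T and NK-like cells, whose difference had a lower bound of 5.77 points. Sorting, dissection and the number of mice follow the library, so with 1 library per group an antibody effect on CD8 T-like cells may exist but cannot be told apart from them.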

How the results depend on the processing

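Chosen after the data were seen were clustering without interferon-induced genes, counting CD8 T cells from genes, thinned list medians, and leaving out a cluster, a sub-cluster or 1 cell. No paired analysis was possible because each group is 1 library. Of the values under alternatives, 1170 lay within the counting interval of the reported value, 296 lay outside it without a called change of sign, and 43 changed sign where that interval excluded 0; the cause was not tested. The interferon-gamma median stayed positive under all alternatives run, from 0.75 to 0.83 over 7 in the monocyte and macrophage clusters and from 0.78 to 1.14 over 8 in neutrophil-like cells, and the CD8 T-like share differed by 0.560 to 1.28 points over 10. By marker scores of single cells, the neutrophil difference was -2.21 points and the CD8 T one 1.17, and by genes the latter was 1.28. With a mitochondrial limit of 20% the non-classical difference was -0.105 points. In the monocyte and macrophage clusters the interferon-gamma median was 0.75 with TMM and 0.78 with each cell's CPM averaged, and the MHC class II median -0.098 with TMM, -0.054 at resolution 2.0, -0.054 without interferon genes, 0.028 with averaged CPM and 0.017 thinned. The neutrophil interferon-gamma median was 1.11 with members of at least 50 UMIs, 1.14 without doublet removal and 1.10 without interferon genes. It was 0.38 thinned in cDC2-like cells, and in non-classical monocyte-like cells 0.50 without interferon genes and 0.43 thinned. The cytotoxic median of T and NK-like cells was 0.28 with averaged CPM and 0.034 thinned. Thinning gave Lcn2 0.19, Orm1 0.16, Gzme 0.25, Gzmd 0.87, Cd55 0.073 and Spp1 0.22, and medians of 0.11 for regulatory T effector genes in monocytes and macrophages and 0.004 in T and NK-like cells, -0.045 for hypoxia in neutrophil-like cells, 0.010 for stress genes in T and NK-like cells and 0.052 in cDC2-like cells, and 0.012 for granule genes in non-classical monocyte-like cells. Averaged CPM gave Gzme 0.48 and Gzmd 0.74, and medians of -0.58 for exhaustion genes in monocytes and macrophages, 0.037 for stress genes in T and NK-like cells and 0.036 for cytotoxic genes in non-classical monocyte-like cells. TMM gave -0.010 for chemokines in monocytes and macrophages, -0.014 for hypoxia in T and NK-like cells and -0.072 for MHC class II in cDC2-like cells. With members of at least 50 UMIs the regulatory T effector median in monocytes and macrophages was 0.16. Without doublet removal the T and NK-like medians were -0.007 for suppressive and 0.16 for inflammatory genes. Without the Ngp and Camp-led cluster, neutrophil-like cells gave Cstdc5 -0.81, Orm1 0.60, Fcnb 0.86, MHC class II 0.11, proliferation 0.22 and hypoxia -0.055. Without the Lyz2 sub-cluster, T and NK-like cells gave Cxcl9 -0.91, Tgfbi -0.010, MHC class II -0.72, suppressive -0.038, chemokines -0.062 and lysosome genes -6.1e-05. Without the cell with most of their UMIs, Gzmf was 1.05, Cd55 0.21, Gzme 7.62 (5.13 to 12.92) and Gzmd 9.07 (6.59 to 14.38), each of the last 2 against 1 UMI. Gzmg was then 6.21 at the floor (lower bound 5.905) against 0 UMIs. That cell held most of the isotype UMIs of these genes.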

Other observations

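All tests by transcript length and GC content in this part were chosen only after the shift they describe was seen, and the values for subsets, smaller classes and receptor genes were added after the data were seen.

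Among smaller classes, cDC1-like cells (157 and 123 cells) had 20 of 21 measured interferon-gamma response genes higher in the anti-PD-1 library, with a median log2 ratio of 0.69 (0.41 to 0.75), and migratory dendritic cells 18 of 21 (0.29, 0.22 to 0.44). B and plasma-like cells had 7 of 18 higher (-0.12, -0.35 to 0.22). Plasmacytoid dendritic cells made up 0.391% and 0.592% of cells, migratory dendritic cells 1.71% and 1.96%, and B and plasma-like cells 0.535% and 0.571%.

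Proliferation genes, higher over all T and NK-like cells, were lower for 9 of 10 measured genes in regulatory T-like cells (median -0.90, -1.59 to -0.47) and for 10 of 12 in NK-like cells (-0.70, -1.06 to -0.071), whose cycling members lie in a sub-cluster of their own. Cytotoxic genes had a median of 0.27 (0.14 to 0.38) in NK-like cells. Regulatory T effector genes were lower for 10 of 14 members over T and NK-like cells (median -0.12, -0.19 to -0.039, but 0.004 after thinning). The receptor gene Trbv12-2 had UMIs in 25 of 91 CD8 T-like cells of the anti-PD-1 library. Its count in the isotype library is not given here, which does not mean that it was absent there. Trbv13-2 had UMIs in 19 of these 91 cells and in 9 of 26 in the isotype library. Trbv13-1 had UMIs in 40 of 184 CD4 T-like cells of the anti-PD-1 library and in 29 of 223 in the isotype library.

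In the monocyte and macrophage clusters the medians were -0.079 for lysosome and lipid handling genes (-0.13 to -0.048, 8 of 14 lower), 0.053 for chemokines, 0.084 for checkpoint ligands (8 of 9 higher), -0.032 for hypoxia and glycolysis genes and 0.12 for dissociation and stress genes (11 of 16 higher). Of the 8 hepatocyte or Hepa1-6 genes 3 were measured there, with a median of -0.35 (-1.06 to 0.016). Erythrocyte RNA gave no median in any class, since fewer than 3 of its 4 genes reached 10 UMIs.

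Some genes differed alike in all 5 compared classes. Lower in the anti-PD-1 library were S100a8, a neutrophil marker (-1.14 to -0.52), the mitochondrial gene mt-Nd3 (-0.80 to -0.47) and short ribosomal protein genes, with log2 ratios of -0.76 to -0.70 for Rps28, -0.75 to -0.65 for Rpl38, -0.76 to -0.65 for Rps29 and -0.75 to -0.59 for Rps21. Brd1 (1.01 to 1.25), Ppp2cb (0.85 to 1.02), Sppl3 (0.77 to 1.60), Plekhm2 (0.75 to 1.13) and Egln1 (0.61 to 1.14) were higher, among 4226 genes considered. These genes were named after their values were seen. Ribosomal protein genes of more than 900 nt had medians of -0.16, -0.15, -0.060, -0.18 and -0.11 relative to all genes, in the order monocyte and macrophage clusters, neutrophil-like, T and NK-like, cDC2-like and non-classical monocyte-like. Genes of at least 50 UMIs were also split by transcript length into 5 groups of equal size. Ribosomal protein and mitochondrial genes were left out of this split, so it does not cover the short ribosomal protein genes named above. The median of the shortest group minus that of the longest was -0.024, -0.12, 0.095, -0.025 and -0.010 in the same order. Within these groups genes of high minus low GC content differed by 0.073, 0.053, 0.045, 0.090 and 0.050.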
